A study of Arabidopsis thaliana with 18 samples.

How the data were processed

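Total RNA of cultured Arabidopsis thaliana cells was extracted with TRIzol, purified with the RNeasy Micro kit and hybridised as biotin-labelled cRNA, per the labels' protocols. The labels name 2 labelling kits, a one-cycle target labelling kit and a 3' IVT expression kit, for different ranges of array codes, and do not tie a code to a sample; which array had which kit is therefore not known here. The 18 arrays fall into 6 groups of 3 by line (wt, VND6, SND1) and time (0 h, 12 h), as their titles state, with replicate numbers 1 to 3 in each group. The labels give 2 µM estrogen as the treatment.

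The values used are the authors' deposited intensity values, 1 linear signal per probe set and array, made with GCOS per the submitters' processing notes. The version and the algorithm are not given in the sources used here. The 2% trimmed mean of the values lay between 500.045 and 500.058 on all 18 arrays, so the table was taken as scaled by the authors to a common trimmed mean and was used as given. The values ranged from 0.0587 to 53986.3, and the median of an array from 103 to 133. Scanner files were not used here. Such scaling assumes that the bulk of transcripts does not move, and GCOS signals near the floor are noisy, so folds of dim probe sets are understated by the pseudocount and uncertain.

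Values were transformed as log2(value + 4.32), where 4.32 is the 10th percentile of the table, and every fold change is on this scale. The 64 control probe sets were left out, and a probe set was tested if it reached the 40th percentile of its own array on at least 3 of the 18 arrays, which left 15715 of 22810. In the annotation given for the array, 13513 probe sets had 1 gene, 503 had several and 8730 had none; 13436 of the first kind were matched to the RefSeq annotation of assembly TAIR10.1, which was used for names and gene classes only. The tested probe sets of 1 gene numbered 8839, for 8737 genes. A probe set without a name is unnamed here, not without a gene. A gene with several probe sets is represented by the one with the highest mean signal. Locus codes are printed where the annotation gives no other symbol.

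Group means of all 18 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that 1 estimate of the spread served all contrasts. The contrasts were 12 h against 0 h in each line, the VND6 and the SND1 response beyond wt (interactions of line and time), the VND6 response minus the SND1 response, and each transformed line against wt at 0 h. P-values are 2-sided and adjusted by Benjamini-Hochberg within a contrast, with calls at an adjusted p under 0.05. The comparisons, the filter, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named below as chosen after seeing the data.

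The 19 gene lists hold 283 genes: NAC regulators, transcription factors downstream of them, secondary wall cellulose, xylan, lignin, cell death and autolysis, microtubules and wall patterning, primary wall, cell cycle, procambium and cambium, phloem, suberin and endodermis, photosynthesis, auxin response, cytokinin response, heat shock, rapid stress and wound response, detoxification and reference genes. Lists with at least 4 tested genes (cell death, xylan and auxin) were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 12 tests of 3 lists in 4 contrasts, and again with an estimated correlation; every camera call that passed also held with the estimated correlation. Smaller lists have counts only. Genes were named by rule: the 10 largest rises and 6 largest falls in each response beyond wt, the 8 largest each way in the difference of the responses and the 5 largest each way elsewhere, among named genes that passed and whose arrays at the 2 ends did not overlap, and up to 4 members of each list with the smallest adjusted p. Symbol families and gene classes were tested after the data were seen.

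Whether replicate numbers pair the arrays was checked by correlating the deviations of same-numbered arrays from their group means across probe sets. The correlations were 0.255 to 0.380 between the times in wt, 0.205 to 0.308 in VND6 cells, 0.188 to 0.326 in SND1 cells and 0.304 to 0.486 between wt and SND1 cells at 0 h, so by the rule of a correlation over 0.1 in every pair the numbers were taken to pair those arrays. Between arrays of different numbers the highest correlations were 0.290, 0.196, 0.173 and 0.338 in the same comparisons, each between replicates 2 and 3, so the numbers set replicate 1 apart and barely tell replicates 2 and 3 from each other. Between wt and VND6 cells at 0 h they were 0.0230 to 0.186 and the numbers were not taken to pair them. The alternatives fixed beforehand were quantile normalization, no filter, a filter at the 60th percentile, no pseudocount, a pseudocount 4 times larger, no intensity trend, fitting only the arrays compared, the replicate number as a block, fry, which tests whether a list moves one way on balance and not against other genes, in place of camera, and each array left out in turn. Chosen after seeing the data were replicates 2 and 3 only, replicates 2 and 3 averaged and counted as 1, and a batch term for replicate 1. Leaving out an array leaves 2 in its group, and the pooled spread of the other groups then carries more of the test.

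The method was tested on simulated data with 15715 genes of which 200 changed. At a log2 change of 2 it recovered 76% of changed genes for wt, 12 h against 0 h, 50% for the VND6 response beyond wt, 46% for the SND1 response beyond wt, 41% for the VND6 response minus the SND1 response, 80% for VND6 against wt at 0 h and 68% for SND1 against wt at 0 h. At a log2 change of 1 the shares were 26%, 11%, 3%, 5%, 22% and 21%. False calls numbered 1 for each response beyond wt and for their difference, 3 for wt, 12 h against 0 h, 6 for VND6 against wt at 0 h and 12 for SND1 against wt at 0 h. The simulated errors were independent between arrays. The closeness of the real replicates 2 and 3 was not simulated, so these shares and false calls may not hold for the real arrays.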

Results

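Suspension-cultured Arabidopsis thaliana cells of 3 kinds were profiled on Affymetrix ATH1 genome arrays. They were wild-type (wt) cells and cells of 2 transformed lines in which estrogen switches on 1 transcription factor of the NAC family. VND6 is known as a switch of vessel differentiation in metaxylem, in which a patterned secondary wall is laid down and the cell then dies. SND1 is known as a regulator of secondary wall formation in fibres. Cells of each kind were sampled at 0 h and at 12 h after 2 µM estrogen was added, with 3 arrays in each of the 6 groups and 18 arrays in all. The question the design addresses is which transcripts respond early to each factor. Each array gave a linear signal for 22810 probe sets, with a median signal of 103 to 133 per array, and 15715 probe sets passed the filter on dim signals and were tested. With 3 arrays per group, the number of arrays limits the precision. The VND6 and SND1 transcripts were not analysed here, so the induction of the factors themselves was not measured. Of the 283 genes on 19 lists fixed beforehand, 41 were named on the array in the annotation used and 38 were tested. None of the 13 NAC regulators, 7 secondary wall cellulose genes, 7 phloem genes, 9 suberin and endodermis genes or 9 cytokinin response genes was among those tested.

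The replicates of each group were not evenly spaced. Over the tested probe sets, Spearman's rho between replicates 2 and 3 was 0.984 to 0.991 in the 6 groups, and between replicate 1 and either of them 0.872 to 0.958. No 2 arrays held identical values. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. For this reason the counts called in each comparison are also given from replicates 2 and 3 only, and with replicates 2 and 3 averaged and counted as 1, both chosen after seeing the data. Time separated the arrays most: the first principal component held 59.2% of the variance and the second 13.0%. On the second, wt replicate 1 at 0 h lay at 41.9, beside VND6 replicates 2 and 3 at 0 h at 37.3 and 31.7, while wt replicates 2 and 3 at 0 h lay at -41.6 and -40.5. VND6 replicate 1 at 0 h lay at 14.3 on it. On the first, wt replicate 1 at 0 h lay at -112, beside wt replicates 2 and 3 at -108 and -109. VND6 replicates 1, 2 and 3 at 0 h lay there at -73.3, -89.9 and -86.9. On the third component (6.54% of variance), wt replicate 1 at 0 h lay at -50.4 and VND6 replicate 1 at 0 h at -54.0. There wt replicates 2 and 3 at 0 h lay at 46.5 and 47.3, and VND6 replicates 2 and 3 at 0 h at 3.61 and 14.7.

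**Figure D1:**
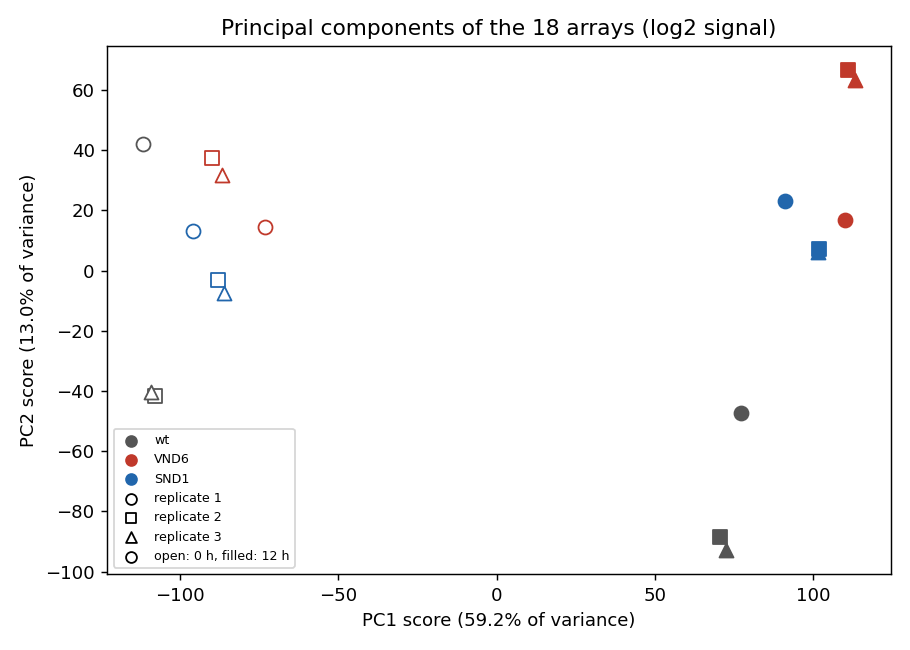
Each point is 1 array on the first (59.2% of variance) and second (13.0%) principal component of log2 signals, with colour for the line, open symbols for 0 h, filled symbols for 12 h and the shape for the replicate. The 0 h and 12 h arrays lie apart on the first component, and wt replicate 1 at 0 h lies at 41.9 on the second, away from wt replicates 2 and 3 at -41.6 and -40.5. On the first it lies at -112, beside wt replicates 2 and 3 at -108 and -109. VND6 replicate 1 at 0 h lies at 14.3 on the second.

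The comparison of wt cells at 12 h with wt cells at 0 h shows what happened in cells without a transgene. It holds both the effect of estrogen and that of 12 h in culture, since no group was sampled at 12 h without estrogen. EXPA4 (AT2G39700), an expansin that loosens cell walls, rose by 6.41 on the log2 scale (SE 0.43, adjusted p = 8.98e-09), from a mean signal of 9.44 ± 6.55 to 1094 ± 238 (SD, n = 3). MCM7 (AT4G02060), a subunit of the replicative DNA helicase, rose by 3.74 (SE 0.30, adjusted p = 4.61e-08), and AUR2, an Aurora kinase of cell division, by 1.79 (SE 0.45). NDB4, a mitochondrial NAD(P)H dehydrogenase, rose by 6.33 (SE 0.52), and GSTU25, a glutathione transferase, by 2.91 (SE 0.63). For GSTU25 the change was 5.54 in replicate 1 and 1.59 in replicates 2 and 3, and 1.89 without wt replicate 1 at 12 h. RCA, the Rubisco activase of photosynthesis, fell by 4.44 (SE 0.39, adjusted p = 1.2e-07), from 1083 ± 507 to 41.7 ± 8.75 (SD, n = 3). GAMMA-VPE, a vacuolar protease, fell by 3.54 (SE 0.28), from 7168 ± 1883 to 598 ± 25.1.

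Of the 7 tested genes of the cell death and autolysis list, 6 fell in wt cells and 1, BETA-VPE, did not pass. Adjusted over the list alone, 6 also fell. The list stood lower than other genes in limma's camera test with a median log2 change of -1.63 (adjusted p = 0.00385, and adjusted p = 0.019 with an estimated correlation). SCPL48, a serine carboxypeptidase-like protein, fell by 2.37, DMP4, a membrane protein linked to senescence, by 1.63, and ALPHA-VPE by 1.49. Without wt replicate 1 at 0 h the ALPHA-VPE value was -0.86; it was -2.48 in replicate 1 and -0.999 in replicates 2 and 3. PASPA3, an aspartic protease used as a marker of developmental cell death, fell by 1.87 (adjusted p = 0.0203), but not without wt replicate 1 at 0 h or wt replicate 1 at 12 h, where the adjusted p reached 0.12 and the value was -1.18 without the second of these. It was -4.21 in replicate 1 and -0.70 in replicates 2 and 3. Of 3 primary wall genes 2 rose, EXPA4 and COB (1.13), which orients cellulose. The rise of COB was lost without wt replicate 2 or 3 at 0 h or wt replicate 1 at 12 h, with an adjusted p up to 0.108. Of 3 cell cycle genes 2 rose, MCM7 and AUR2. Of 3 lignin genes 1 rose, HCT (0.91), an enzyme of the lignin pathway, though not without wt replicate 2 or 3 at 12 h (adjusted p up to 0.0767), and its value was 0.20 in replicate 1 and 1.26 in replicates 2 and 3. Of 2 procambium genes LHW, a vascular transcription factor, rose by 0.53, a call lost without any 1 array other than wt replicate 2 at 0 h (adjusted p up to 0.131). Of 6 auxin response genes GH3.1 rose by 2.45 and GH3.3 fell by 2.29, both enzymes that conjugate auxin, and the list as a whole did not pass (adjusted p = 0.727). Adjusted over the list alone, 1 auxin gene rose and 0 fell, against 1 and 1 over all probe sets. The fall of GH3.3 was lost without wt replicate 1 at 0 h or wt replicate 2 or 3 at 12 h (adjusted p up to 0.239), and its value was -1.16 without the first of these. Of 2 heat shock genes 1 fell, HSP17.6C by 1.89, but not without wt replicate 2 or 3 at either time (adjusted p up to 0.0885), and its value was -0.24 in replicate 1 and -2.72 in replicates 2 and 3. The 4 xylan genes did not pass, singly or together (adjusted p = 0.813), nor did the 2 stress genes or the 2 reference genes, SAND at -0.21 and TIP41-LIKE at -0.02.

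In all, 8501 of the 15715 probe sets (54.1%) changed in wt cells, 5043 higher and 3458 lower, by limma with an adjusted p under 0.05. Among named genes of no list, AT5G59240 rose by 6.25 and AT1G23410 by 5.89, while AT2G32150 (-9.89), AT3G61930 (-9.15), AT3G15450 (-8.98), AT1G19530 (-8.09) and AT3G15630 (-7.57) fell. The count was 10785 with replicates 2 and 3 only and 5818 with them averaged. The median log2 change over all tested probe sets was 0.196, and 0.0784 after quantile normalization, so small changes are read against that shift.

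The VND6 response beyond wt is the change from 0 h to 12 h in VND6 cells minus that in wt cells, which takes off what estrogen and time did without the transgene. PRX72 (AT5G66390), a class III peroxidase of lignin polymerisation, rose by 8.31 more than in wt on the log2 scale (SE 0.82, adjusted p = 1.06e-05); its mean signal in VND6 cells went from 5.24 ± 6.61 to 1629 ± 24.6 (SD, n = 3), and in wt cells it was 4.64 ± 3.23 at 12 h. PRX66, another class III peroxidase, rose by 2.78 (SE 0.65). Of the cell death genes, SCPL48 rose by 5.82 more than in wt (SE 0.64, adjusted p = 3.44e-05), reaching a signal of 20702.5 ± 2537, and DMP4 by 4.80 more (SE 0.45, adjusted p = 8.01e-06). IRX15 (AT3G50220), which acts in the deposition of xylan, rose by 3.01 (SE 0.59, adjusted p = 0.00402), and KIN13A, a kinesin that depolymerises microtubules, by 1.96 (SE 0.32). LBD16, an auxin-responsive transcription factor of lateral root formation, fell by 2.62 relative to wt (SE 0.61, adjusted p = 0.0114), from 1837 ± 837 to 376 ± 350.

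Of the 3 lignin genes 2 rose and 1 did not pass, and adjusted over the list alone 2 rose and 1, HCT, stood lower than in wt (-0.95). Within VND6 cells HCT changed by -0.04 (limma adjusted p = 0.911), against 0.91 in wt cells. Of the 7 cell death genes 3 had a higher response than in wt, SCPL48, DMP4 and PASPA3 (2.81), and 4 did not pass, SCPL49 at 0.43, GAMMA-VPE at -0.12, ALPHA-VPE at -0.68 and BETA-VPE at -0.76. Adjusted over the list alone, 3 were higher. The cell death list stood higher than other genes (adjusted p = 0.00385, and 0.019 with an estimated correlation), with a median log2 of 0.427 and a mean of 1.76. Much of that mean comes from the fall in wt cells, where the list's mean was -1.62. Within VND6 cells SCPL48 changed by 3.45 and DMP4 by 3.17. GAMMA-VPE changed there by -3.66, ALPHA-VPE by -2.17, SCPL49 by -0.45 and BETA-VPE by -0.31. In VND6 cells themselves PASPA3 changed by 0.95 and did not pass (adjusted p = 0.223, but 0.0395 with only the arrays compared and 0.0381 with replicates 2 and 3 only), against -1.87 in wt, and its response beyond wt was 5.15 in replicate 1 and 1.64 in replicates 2 and 3. At 0 h DMP4 stood at -1.31 against wt in VND6 cells (adjusted p = 0.02), a call lost without wt replicate 3 or VND6 replicate 2 or 3 at 0 h (up to 0.097), with only the arrays compared (0.183) and with replicates 2 and 3 averaged (0.347). The PASPA3 call (adjusted p = 0.0473) held without wt replicate 3 at 0 h, wt replicate 2 at 12 h or VND6 replicate 1 at 12 h and was lost without any 1 of the other 9 arrays, with an adjusted p up to 0.104; it was also lost without a filter, without a pseudocount and with only the arrays compared. Of the 4 xylan genes 1 rose, IRX15, and 3 did not pass, among them IRX15L at 2.17 (adjusted p = 0.121), IRX10 at 0.84 (adjusted p = 0.0725) and IRX10L at 0.17. Adjusted over the list alone, 3 xylan genes rose, and the list stood higher than other genes with a median log2 of 1.51 (adjusted p = 0.00774, and 0.035 with an estimated correlation). With replicates 2 and 3 only, the xylan test gave an adjusted p = 0.0508.

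Of the 6 auxin response genes 2 fell relative to wt, LBD16 and LBD29 (by 2.73), and 4 did not pass; adjusted over the list alone 3 fell. The auxin list had a median log2 of -2.28 and did not pass in camera (adjusted p = 0.0896, and 0.38 with an estimated correlation), but passed with the replicate number as a block (adjusted p = 0.00408) and without wt replicate 1 at 0 h (0.0226), wt replicate 2 at 12 h (0.0399), wt replicate 3 at 12 h (0.0302) or VND6 replicate 1 at 12 h (0.0325). The LBD29 call (adjusted p = 0.0497) held without wt replicate 1 at 0 h, wt replicate 3 at 12 h or VND6 replicate 1 at 12 h and was lost without any 1 of the other 9 arrays (adjusted p up to 0.136), as under quantile normalization, both other filters and no pseudocount. LBD29 already stood 2.24 higher than wt in VND6 cells at 0 h (adjusted p = 0.0362), a call that held without wt replicate 1 and was lost without any 1 of the other 5 arrays at 0 h (up to 0.134), without a filter and without a pseudocount. Of 3 cell cycle genes MCM7 fell by 1.72 relative to wt (SE 0.42), 2 did not pass, and 2 fell when adjusted over the list alone. Within VND6 cells MCM7 rose by 2.02, from a level 1.46 higher than wt at 0 h (adjusted p = 0.00792). Of 2 procambium genes LHW fell by 1.29. The single microtubule gene tested, KIN13A, and the single detoxification gene, GSTU25 (3.79), rose; for GSTU25 the response was 0.63 in replicate 1 and 5.38 in replicates 2 and 3. C3H14, the single transcription factor tested downstream of the NAC factors, stood at 2.27 and did not pass over all probe sets (limma adjusted p = 0.141). It rose over its list alone, where a single gene leaves the p-value unadjusted. None of the 3 primary wall, 2 heat shock, 2 stress or 2 reference genes passed, nor the single photosynthesis gene.

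In the VND6 response beyond wt, 2174 probe sets (13.8%) passed in limma, 918 higher and 1256 lower, and after quantile normalization 1041 higher and 1106 lower; the median log2 over all tested was -0.216, and -0.117 after quantile normalization. The genes outside the lists with the largest rises were AT1G70500 (9.99, SE 0.69), from a signal of 16.4 ± 11.4 to 17258 ± 2387 in VND6 cells (SD, n = 3), AT5G26330 (9.41), AT3G52900 (9.28) and AT3G47400 (9.26). The largest negative responses were smaller: IQD24, of a family of calmodulin-binding proteins, at -3.46, AT5G04310 at -3.27 and AT1G64405 at -3.25. A second probe set of AT5G04310 gave -3.92. The IQD24 call was lost without VND6 replicate 2 at 12 h (adjusted p = 0.0536). The count was 7585 with replicates 2 and 3 only and 126 with them averaged, 116 of them higher and 10 lower. With them averaged, PRX72, SCPL48, DMP4 and the 4 genes with the largest rises still passed, and IRX15, PRX66, KIN13A, LBD16 and MCM7 did not. It was 1049 when only the arrays of the 4 groups were fitted, 535 higher and 514 lower. Without 1 array it came to 1380 (wt replicate 2 at 12 h), 1385 (wt replicate 3 at 12 h), 3437 (VND6 replicate 1 at 12 h), 1099 (VND6 replicate 2 at 12 h) and 1145 (VND6 replicate 3 at 12 h).

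The SND1 response beyond wt is the same difference for the SND1 line. Xylan genes rose: IRX15 by 6.57 on the log2 scale (SE 0.59, adjusted p = 9.32e-06), from a mean signal of 2.82 ± 0.214 to 595 ± 105 in SND1 cells (SD, n = 3), IRX15L by 4.52 (SE 0.90, adjusted p = 0.0071) and IRX10, of the xylan backbone, by 1.36 (SE 0.30, adjusted p = 0.0141). Cell death genes also rose relative to wt, DMP4 by 5.17 (SE 0.45), SCPL48 by 4.75 (SE 0.64) and PASPA3 by 4.13 (SE 0.90, adjusted p = 0.0126), the last by 6.58 in replicate 1 and 2.91 in replicates 2 and 3. Within SND1 cells these 3 changed by 3.54, 2.37 and 2.27, and in wt cells by -1.63, -2.37 and -1.87. CXE20, of the carboxylesterase family, rose by 6.31 (SE 0.69). PRX72 stood at 0.31 (adjusted p = 0.864), with a signal of 2.42 ± 0.673 in SND1 cells at 12 h (SD, n = 3). MCM7 fell by 2.69 relative to wt (SE 0.42, adjusted p = 0.00121): it went from 262 ± 46.7 to 543 ± 29.4 in SND1 cells and from 74.4 ± 23.8 to 1026 ± 206 in wt cells. At 0 h MCM7 stood 1.79 higher than wt in SND1 cells (adjusted p = 0.00504).

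Of the 4 xylan genes 3 rose and IRX10L, at 0.15, did not pass; adjusted over the list alone 3 rose. The list stood higher than other genes with a median log2 of 2.94 (adjusted p = 4.05e-05, and 0.0049 with an estimated correlation). Of the 7 cell death genes 3 had a higher response than in wt and 4 did not pass, SCPL49 at 0.51, GAMMA-VPE at 0.60, ALPHA-VPE at -0.25 and BETA-VPE at -0.26. Adjusted over the list alone, 3 were higher, and the list passed with a median log2 of 0.596 and a mean of 2.09 (adjusted p = 4.69e-05, and 0.0049 with an estimated correlation). Much of that mean comes from the fall in wt cells, where the list's mean was -1.62. Within SND1 cells GAMMA-VPE changed by -2.95, ALPHA-VPE by -1.74, SCPL49 by -0.37 and BETA-VPE by 0.20. None of the 3 lignin genes passed. Of the 6 auxin response genes LBD16 fell by 2.54 and 5 did not pass, over all probe sets and adjusted over the list alone. The auxin list had a median log2 of -1.70 and did not pass (adjusted p = 0.0896, and 0.38 with an estimated correlation), but passed with the replicate block (adjusted p = 0.00408), with only the arrays of the groups compared (0.0392), and without wt replicate 1 at 0 h (0.0173), wt replicate 2 at 12 h (0.0368), wt replicate 3 at 12 h (0.0191) or SND1 replicate 2 at 0 h (0.0484). Of 3 cell cycle genes MCM7 fell and 2 did not pass, and of 2 procambium genes LHW fell by 1.18. KIN13A rose by 1.47 (SE 0.32) and GSTU25 by 3.56, its response being 0.19 in replicate 1 and 5.24 in replicates 2 and 3. C3H14 stood at 2.64 and did not pass over all probe sets (limma adjusted p = 0.130). It rose over its list alone, where a single gene leaves the p-value unadjusted. No gene of the primary wall, heat shock, stress, photosynthesis or reference lists passed.

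Some of these calls lay near the threshold and were lost when 1 array was left out. With 1 array left out the value ranged from -2.68 to -2.38 for LBD16, from 2.94 to 4.58 for GSTU25 and from -1.37 to -1.08 for LHW. The LBD16 call (adjusted p = 0.0233) was lost without replicate 2 or 3 of wt at 12 h, of SND1 at 0 h or of SND1 at 12 h (adjusted p up to 0.0621). The GSTU25 call (adjusted p = 0.028) was lost without the same 6 arrays or wt replicate 2 at 0 h (up to 0.0783). The LHW call (adjusted p = 0.0244) held without wt replicate 1 or 2 at 0 h, wt replicate 1 at 12 h or SND1 replicate 1 at 12 h and was lost without any 1 of the other 8 arrays (up to 0.0744).

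In the SND1 response beyond wt, 923 probe sets (5.87%) passed in limma, 546 higher and 377 lower; the median log2 over all tested was -0.202, and -0.130 after quantile normalization. The genes outside the lists with the largest rises were AT3G47400 (9.05, SE 0.64, adjusted p = 8.23e-07), AT5G60530 (8.20), AT5G16230 (7.46, SE 0.88) and AT1G54790 (7.23). AT4G21870 fell by 2.53, with -4.24 in replicate 1 and -1.67 in replicates 2 and 3. With replicates in numbered blocks the count was 1658, 754 higher and 904 lower. It was 5469 with replicates 2 and 3 only and 62 with them averaged, 61 of them higher and 1 lower; IRX15, DMP4 and CXE20 still passed with them averaged, and IRX15L, IRX10, SCPL48, PASPA3 and MCM7 did not. It was 1674 with replicate 1 against replicates 2 and 3 as a batch term, also chosen after seeing the data. Without 1 array it came to 526 (wt replicate 2 at 12 h), 498 (wt replicate 3 at 12 h), 487 (SND1 replicate 2 at 0 h), 515 (SND1 replicate 3 at 0 h), 463 (SND1 replicate 2 at 12 h) and 474 (SND1 replicate 3 at 12 h).

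**Figure D2:**
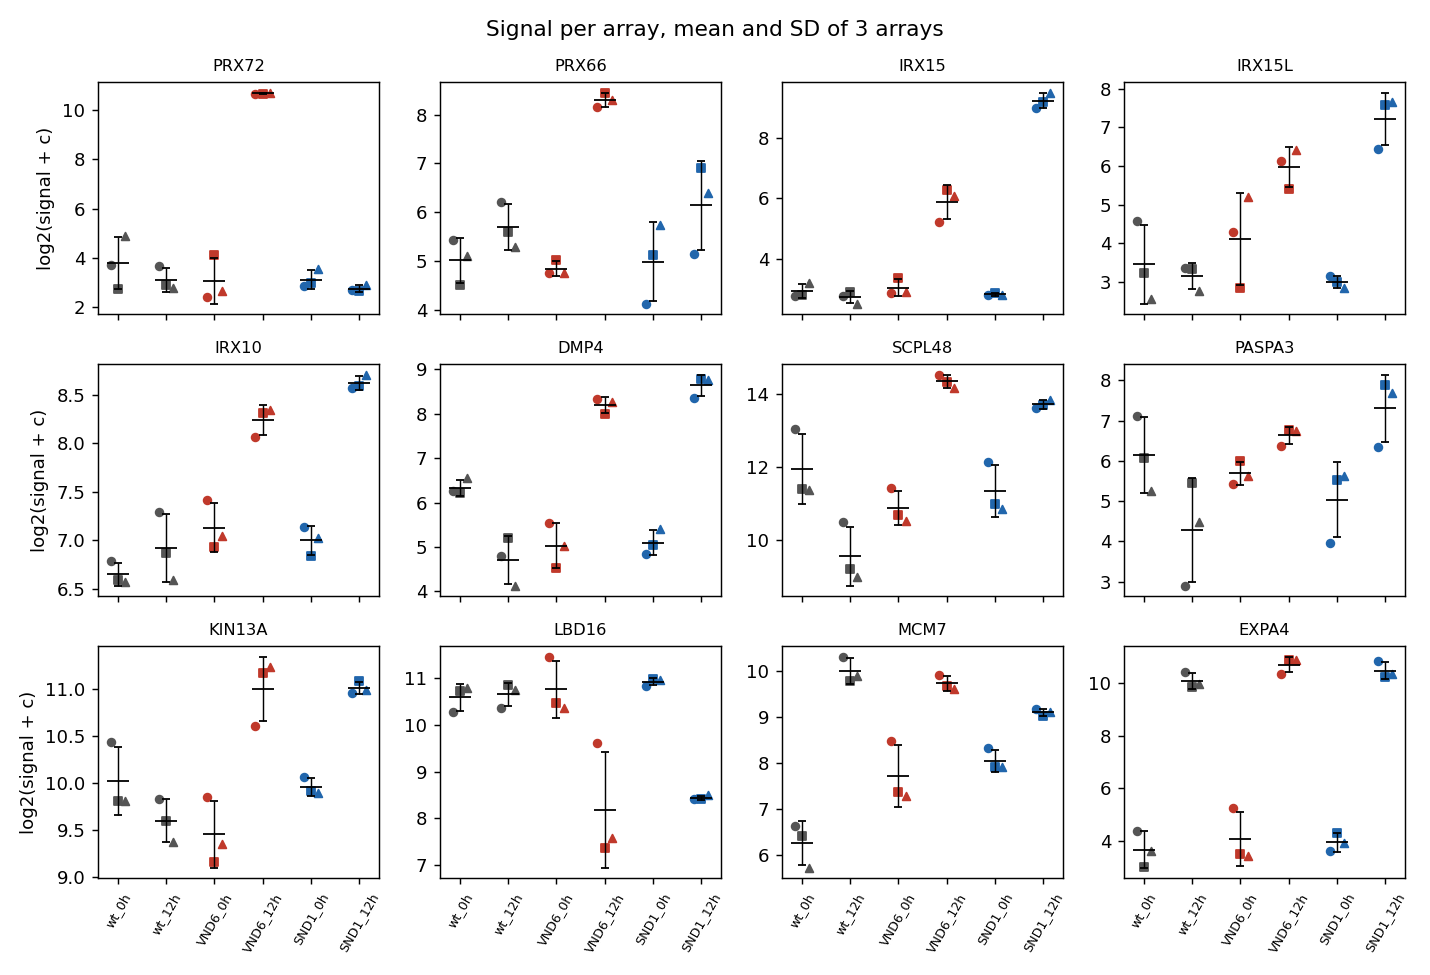
Signals of 12 named genes as log2(signal + 4.32) on the y axis, by line and time, with the mean and SD of 3 arrays in black and a symbol for each replicate. At 12 h the mean of PRX72 was 10.67 in VND6 cells and 2.75 in SND1 cells, and that of IRX15 was 5.86 in VND6 cells and 9.21 in SND1 cells.

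Whether the 2 factors differed was tested as the VND6 response minus the SND1 response, which needs no wt arrays. PRX72 rose 7.99 more on the log2 scale in VND6 cells than in SND1 cells (SE 0.82, adjusted p = 7.46e-05). IRX15 rose less in VND6 cells, with a difference of -3.56 (SE 0.59, adjusted p = 0.00665) and signals at 12 h of 56.7 ± 21.1 in VND6 cells and 595 ± 105 in SND1 cells (SD, n = 3). AT5G26330 (7.75, SE 0.72), AT3G52900 (7.44) and AT1G62170 (7.31) rose more in VND6 cells. AT5G16230 rose in SND1 cells from 12.7 ± 7.98 to 660 ± 284 and in VND6 cells stood at 15.1 ± 3.13 at 0 h and did not pass, a difference of -5.50 (SE 0.88, adjusted p = 0.00464).

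Of the 4 xylan genes 1 had a smaller response in VND6 cells, IRX15, and 3 did not pass; adjusted over the list alone the response was smaller for 2. The xylan list stood lower than other genes, with a median log2 of -1.43 (adjusted p = 0.00158, and 0.019 with an estimated correlation), while with replicates 2 and 3 only it did not pass (adjusted p = 0.243). Of 3 lignin genes PRX72 passed; adjusted over the list alone 2 were higher and 1 lower in VND6 cells. The 7 cell death genes tested, of 15 on the list, did not pass singly or as a list (camera adjusted p = 0.249), nor did the 6 auxin genes (camera adjusted p = 0.765). PASPA3 stood at -1.32 (SE 0.90) and SCPL48 at 1.08 (SE 0.64). In the simulated data this contrast recovered 41% of genes at a log2 change of 2 and 5% at 1. Differences of that size may therefore have been missed. The auxin test turned direction, with an adjusted p of 0.763, 0.899 and 0.925, without VND6 replicate 1 at 0 h and VND6 replicates 2 and 3 at 12 h in turn. No gene of the other lists passed.

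In all, 117 probe sets (0.745%) passed for the VND6 response minus the SND1 response, 69 higher and 48 lower in VND6 cells, against 57 and 60 with the replicate block. TET13, a tetraspanin, was among them at -3.70 (adjusted p = 0.0494), a call that held without VND6 replicate 1 at 12 h or SND1 replicate 2 at 0 h and was lost without any 1 of the other 10 arrays (adjusted p up to 0.165). The count was 2586 with replicates 2 and 3 only, 1183 higher and 1403 lower, and 12 with them averaged, where PRX72 passed and IRX15 and AT5G16230 did not. Without 1 array it came to 194 (VND6 replicate 1 at 0 h), 77 (VND6 replicate 2 at 0 h), 74 (VND6 replicate 2 at 12 h), 66 (VND6 replicate 3 at 12 h) and 75 (SND1 replicate 2 at 12 h).

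The responses of the 2 lines overlapped. From 0 h to 12 h, 8400 probe sets changed in VND6 cells (4519 higher, 3881 lower) and 7951 in SND1 cells (4374 higher, 3577 lower). Of these 3613 were higher in both, against 1258 for independent lists, and 3078 were lower in both, against 883. Leaving out the probe sets called in wt, 716 were higher in both, against 159, and 675 lower in both, against 151. Probe sets that changed in wt without passing remain among these, so this excess may still hold effects of estrogen and time. The VND6 and SND1 comparisons share no arrays, and their log2 changes correlated across probe sets at Pearson's r = 0.899, where probe sets are not independent replicates. This r ranged from 0.844 without a filter to 0.923 with the stricter filter over the alternatives. The change in wt cells correlated with that in VND6 cells at 0.749 (0.692 to 0.775 over the alternatives) and in SND1 cells at 0.807 (0.757 to 0.832), and overlapped with the first in 3256 probe sets higher and 2624 lower, and with the second in 3322 higher and 2648 lower. With replicates 2 and 3 only, the changes numbered 11006 in VND6 and 10525 in SND1 cells, and 4671 were higher and 4205 lower in both. With replicates 2 and 3 averaged, the changes numbered 5238 in VND6 cells and 4955 in SND1 cells, and 2136 were higher and 1844 lower in both. Without the probe sets called in wt, these 2 alternatives gave 740 higher and 777 lower, and 504 higher and 399 lower.

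The 2 responses beyond wt share the wt arrays. Both were higher for 406 probe sets, against 31.9 for independent lists, and lower for 292, against 30.1. With replicates 2 and 3 only they numbered 1728 and 2738, and with these averaged 46 and 0 in limma, where 459 were lower in both at an unadjusted p under 0.05. Without a filter they were 333 and 179, with the replicate block 559 and 739, and with the batch term 616 and 693. In 20 simulations all 18 arrays were drawn as independent noise without any change, and both responses used the same simulated wt arrays. Limma then called 0 probe sets in both. With no change simulated, an adjusted p leaves almost no calls in either response. That 0 therefore does not show how many of the 406 and 292 come from the shared wt arrays. The closeness of replicates 2 and 3 was not simulated, so the simulated values may understate what shared controls give. The correlation of the responses was 0.785 (0.722 to 0.817 over the alternatives), against 0.497 in the simulation, and their covariance 0.902, against 0.203. With 3 wt arrays at each time no split leaves 2 on each side, so part of the excess may come from the shared controls. SCPL48, DMP4, KIN13A and GSTU25 were among the genes with higher responses in both, and LBD16, MCM7 and LHW among those with lower responses in both. Of the 406, 18 differed between the 2 factors by the test of the difference, and of the 292 none passed that limma test, where 26 had an unadjusted p under 0.05. The median response of the 406 was 2.35 in VND6 cells and 2.20 in SND1 cells.

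**Figure D3:**
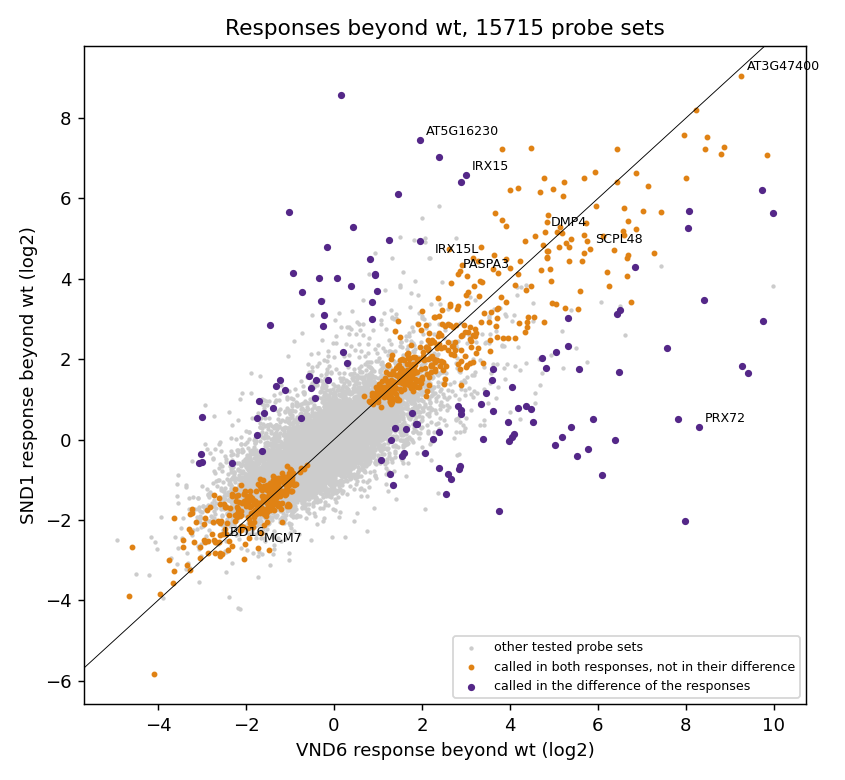
Each point is 1 of 15715 probe sets, with the VND6 response beyond wt on the x axis and the SND1 response beyond wt on the y axis, both in log2. Orange points are those among the 406 higher and 292 lower in both that were not called different between the factors, purple points are the 117 called different, and Pearson's r over all points was 0.785.

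At 0 h probe sets were called between each transformed line and wt, a comparison of where each line started. Across probe sets, the difference in replicate 1 correlated with that in replicates 2 and 3 at -0.0116 for VND6 and 0.110 for SND1. None of the limma calls in these 2 comparisons held with replicates 2 and 3 averaged, so whether the lines themselves differed stays open. AMY1 (AT4G25000), an alpha-amylase, stood lower than wt in SND1 cells (log2 -2.92, SE 0.46, adjusted p = 0.0035), with signals of 156 ± 96.5 and 1086 ± 108 (SD, n = 3). SFP1, of a family of sugar transporters, stood at -1.91 in SND1 cells (SE 0.27, adjusted p = 0.00183). AT2G41730 stood higher in both lines, by 4.92 in VND6 cells (SE 0.64, adjusted p = 0.00056) and by 5.56 in SND1 cells (SE 0.64, adjusted p = 0.000571); its probe set has a suffix that marks probes shared with other sequences. AT5G62550 stood higher by 3.47 and 3.89, and AT3G46700 lower in VND6 cells at -4.56 (SE 0.49). Among the lowest in VND6 cells at 0 h was AT3G30670, annotated as a pseudogene, at -5.55 (SE 0.82, adjusted p = 0.00119), with -2.57 in replicate 1 and -7.03 in replicates 2 and 3.

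For VND6 against wt at 0 h, 1338 probe sets passed, 754 higher and 584 lower. The log2 difference between the lines in replicate 1 correlated with that in replicates 2 and 3 at -0.0116 across probe sets, and the differences in replicates 2 and 3 with each other at 0.821. At 12 h the first of these values was 0.595. The count was 7541 with replicates 2 and 3 only, 2262 with the batch term, 45 when only these 6 arrays were fitted, and 0 with replicates 2 and 3 averaged, where limma gave 1535 at an unadjusted p under 0.05. Without 1 array it came to 2939 (wt replicate 1), 643 (wt replicate 2), 634 (wt replicate 3), 540 (VND6 replicate 2) and 735 (VND6 replicate 3).

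For SND1 against wt at 0 h, 368 probe sets passed, 295 higher and 73 lower; after quantile normalization 284 passed, 205 higher and 79 lower. The difference in replicate 1 correlated with that in replicates 2 and 3 at 0.110 across probe sets. With the replicate number as a block the count was 583, 476 higher and 107 lower. It was 4510 with replicates 2 and 3 only, 730 with the batch term, 1 when only these 6 arrays were fitted, and 0 with replicates 2 and 3 averaged, where limma gave 931 at an unadjusted p under 0.05. Without 1 array it came to 846 (wt replicate 1), 206 (wt replicate 2), 153 (wt replicate 3), 221 (SND1 replicate 1), 102 (SND1 replicate 2) and 103 (SND1 replicate 3).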

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

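The tests of RNA degradation, of a shared batch, of exchanged array labels, of regroupings that keep numbered pairs together and of a difference present only in replicates 2 and 3 were chosen after the result was seen, as were the fits with replicates 2 and 3 only, with these averaged and with a batch term. The results that follow first are differences between lines in their change from 0 h to 12 h, each tested by the interaction of line and time in limma, and are given as log2 values unless said otherwise.

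In the VND6 response beyond wt 2174 probe sets differed. Genes with a higher response than in wt were AT1G70500 (9.99), AT5G26330 (9.41), AT3G52900 (9.28), AT3G47400 (9.26), AT3G27200 (8.42), PRX72 (8.31), AT5G60530 (8.23), AT2G04850 (8.05), AT1G62170 (7.81), AT5G38610 (7.56), SCPL48 (5.82), DMP4 (4.80), GSTU25 (3.79), IRX15 (3.01), PASPA3 (2.81), PRX66 (2.78) and KIN13A (1.96). Genes with a lower response were IQD24 (-3.46), AT5G04310 (-3.27), AT1G64405 (-3.25), AT5G24600 (-3.23), AT4G24050 (-3.23), AT1G62770 (-3.06), LBD29 (-2.73), LBD16 (-2.62), MCM7 (-1.72) and LHW (-1.29). For AT5G24600 the value was 0.13 in replicate 1 and -4.91 in replicates 2 and 3. Some of these genes already stood higher than wt in VND6 cells at 0 h: AT4G24050 by 3.31 (adjusted p = 0.0031), with means of 4.91 in VND6 and 4.82 in wt cells at 12 h, LBD29 by 2.24 (adjusted p = 0.0362), AT5G24600 by 2.12 (adjusted p = 0.0269) and MCM7 by 1.46 (adjusted p = 0.00792). At 0 h the LBD29 call held only without wt replicate 1 (otherwise up to 0.134), and that of AT5G24600 was lost without replicate 2 or 3 of either line (up to 0.121). MCM7 rose by 2.02 within VND6 cells, and PASPA3 changed there by 0.95 (adjusted p = 0.223), with a response beyond wt of 5.15 in replicate 1 and 1.64 in replicates 2 and 3. The GSTU25 response was 0.63 in replicate 1 and 5.38 in replicates 2 and 3. The call of AT1G62770 was lost without VND6 replicate 2 or 3 at 12 h (adjusted p up to 0.0539). The xylan list (adjusted p = 0.00774) and the cell death list (adjusted p = 0.00385) stood higher.

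In the SND1 response beyond wt 923 probe sets differed. Higher responses than in wt were those of AT3G47400 (9.05), AT5G60530 (8.20), AT5G16230 (7.46), AT1G54790 (7.23), AT5G14510 (6.64), IRX15 (6.57), AT4G01240 (6.52), AT5G57500 (6.41), CXE20 (6.31), AT1G52050 (6.11), DMP4 (5.17), SCPL48 (4.75), IRX15L (4.52), PASPA3 (4.13), GSTU25 (3.56), KIN13A (1.47) and IRX10 (1.36). Lower responses were those of AT5G63700 (-3.29), AT1G62770 (-2.94), AT1G60180 (-2.81), AT5G20790 (-2.74), MCM7 (-2.69), LBD16 (-2.54), AT4G21870 (-2.53) and LHW (-1.18). At 0 h AT1G60180 stood 2.31 higher than wt in SND1 cells (adjusted p = 0.0337, held only without wt replicate 1, otherwise up to 0.153) and MCM7 1.79 higher (adjusted p = 0.00504), and MCM7 rose by 1.05 within SND1 cells, a call lost with replicates 2 and 3 averaged (adjusted p = 0.0922). The 0 h calls of AT4G24050, LBD29, AT5G24600, AT1G60180, DMP4 and of MCM7 in both lines were lost with only the 6 arrays fitted and with replicates 2 and 3 averaged (adjusted p = 0.0527 or higher). The response was 0.19 in replicate 1 and 5.24 in replicates 2 and 3 for GSTU25, -1.10 and -3.56 for AT5G20790, and -4.24 and -1.67 for AT4G21870. Leaving out 1 array ended some of these calls. That of AT5G20790 was lost without replicate 2 of wt at 12 h or of SND1 at 12 h, or SND1 replicate 2 or 3 at 0 h (adjusted p up to 0.0658). The call of AT5G63700 held only without wt replicate 2 at 0 h, wt replicate 1 at 12 h or SND1 replicate 2 at 12 h (otherwise up to 0.114), that of AT1G62770 only without wt replicate 1 at 0 h or SND1 replicate 1 at 12 h (up to 0.0867), and that of AT1G60180 only without wt replicate 1 at 0 h or wt replicate 3 at 12 h (up to 0.0961). The xylan list (adjusted p = 4.05e-05) and the cell death list (adjusted p = 4.69e-05) stood higher.

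In the VND6 response minus the SND1 response 117 probe sets differed. Values were higher in VND6 cells for PRX72 (7.99), AT5G26330 (7.75), AT3G52900 (7.44), AT1G62170 (7.31), AT1G23460 (6.41), AT3G63050 (6.02), AT3G54520 (5.94) and AT5G64690 (5.52), and lower for AT5G16230 (-5.50), AT3G03770 (-4.93), AT1G52060 (-4.86), AT1G52050 (-4.65), AT2G43870 (-4.36), AT3G13820 (-3.93), TET13 (-3.70), AT3G56230 (-3.68) and IRX15 (-3.56). The call of AT3G63050 was lost without VND6 replicate 3 at 12 h (adjusted p = 0.052), that of AT5G64690 without VND6 replicate 2 at 0 h or replicate 2 or 3 at 12 h (up to 0.0716) and that of AT3G03770 without SND1 replicate 2 or 3 at 12 h (up to 0.0572). The call of AT1G52050 held only without VND6 replicate 3 or SND1 replicate 1 at 0 h (otherwise up to 0.127), that of AT2G43870 only without VND6 replicate 1 at 0 h, VND6 replicate 2 at 12 h or SND1 replicate 1 at 12 h (up to 0.13), and that of AT3G13820 only without VND6 replicate 1 at 0 h or VND6 replicate 1 or 3 at 12 h (up to 0.117). The replicate block also ended the calls of AT2G43870 and AT3G13820. The xylan list stood lower in VND6 cells (adjusted p = 0.00158).

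Replicate 1 stood apart from replicates 2 and 3 in all 6 groups, with 3546 probe sets called between them. The values argue against scaling, since 3762 were called after quantile normalization, and against RNA degradation, since over 3 control transcripts in 6 groups replicate 1 had the highest ratio of 3' to 5' signals in 4 of 18 sets of 3 arrays and the lowest in 8. A shift shared by replicate 1 shows in the values, since the 3546 calls come from 1 replicate 1 term fitted across all 6 groups. The replicate 1 deviations correlated above 0 in 14 of 15 pairs of groups (median 0.233, lowest -0.127). On the third principal component (6.54% of variance) replicate 1 lay at -54.4 to -18.7 and the other arrays at -5.32 to 47.3. The cause of the shift, such as the labelling kit, stays open, as no label ties a kit to an array. Exchanged labels of wt and VND6 replicate 1 at 0 h may also play a part and stay open, since the 0 h difference between these lines in replicate 1 correlated at -0.0116 with that in replicates 2 and 3, the sign was opposite for 66 of the 100 largest, and for 58.5% of 335 probe sets that differed at both times, against 35.8% at 12 h. On the first principal component wt replicate 1 at 0 h lay at -112, beside wt replicates 2 and 3 (-108 and -109). On the second it lay at 41.9, beside VND6 replicates 2 and 3 (37.3 and 31.7), and VND6 replicate 1 lay at 14.3. On the third it lay at -50.4, beside VND6 replicate 1 (-54.0). There VND6 replicates 2 and 3 lay at 3.61 and 14.7, and wt replicates 2 and 3 at 46.5 and 47.3. Beyond the shared shift, those values allow both a partly exchanged sample and cultures that differed more between replicates than between lines. No biological explanation was tested.

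Probe sets of genes annotated as pseudogenes stood lower in VND6 than in wt cells at 0 h, 37 of 216 lower and 5 higher, with a median log2 of -1.08, while 126 were lower with replicates 2 and 3 only and 0 in limma with these averaged, where 30 were lower at an unadjusted p under 0.05. The values argue against probes shared between copies, since 15.3% of 137 probe sets with the plain suffix were lower, against 3.72% of all tested and 20.3% of the class with other suffixes. They argue against low signal, since of 1080 picks of genes matched on signal 3.06% were lower, against 17.1% of the class. The picks were the 5 nearest genes to each member, and a gene could be picked more than once. The values also argue against scaling, with 45 lower after quantile normalization. The difference lay in replicates 2 and 3 (median -1.56) and not in replicate 1 (0.0264), which is what a split between the replicates would give, while a full exchange of labels would turn the sign in replicate 1. Whether the lines themselves differ in these transcripts may depend on which replicates are right, and stays open.

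A response beyond wt can come from a line that started apart at 0 h. Of the 918 probe sets higher in the VND6 response beyond wt, 15.6% had a larger difference between the lines at 0 h than at 12 h, and 777 were also called higher at 12 h, so the starting point is not the source of most of them. Their median difference was 1.70 at 12 h and -0.214 at 0 h. Of the 1256 lower ones 38.1% had a larger difference at 0 h, 787 were called lower at 12 h and 369 were called higher at 0 h, with medians of -0.906 and 0.604, so for these the starting point could account for part and stays open. An effect of VND6 is the biological explanation the design offers, and it was not tested apart from these values.

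Other splits of the arrays were counted for each comparison. The 10 splits of 6 arrays are too few for a share under 0.05: in each of these 5 comparisons 1 split, the real one, gave as many calls. The real and the highest other counts were 8501 and 1 for wt, 12 h against 0 h, 8400 and 0 for VND6, 7951 and 0 for SND1, 1338 and 657 for VND6 against wt at 0 h, and 368 and 0 for SND1 against wt at 0 h; for VND6 against wt the highest was 586 among the splits that part every numbered pair. The counts of 0 are limma calls at an adjusted p under 0.05. Of 100 drawn regroupings of the lines within each time, 4 gave as many calls for the VND6 response beyond wt, a share under 0.05 among regroupings that take no account of the numbered pairs. The 3 others gave 4241, 4201 and 3908, against 2174. The first exchanged wt and VND6 replicates 2 and 3 at 0 h, and so follows the replicate structure. It is the mirror of exchanged replicate 1 labels, with the 0 h difference between the lines turned in sign. It therefore adds the differences at both times and does not give the count for exchanged replicate 1 labels. The second exchanged wt replicates 2 and 3 with VND6 replicates 1 and 2 at 0 h, which parts VND6 replicates 2 and 3 and does not follow that structure. The last exchanged all 12 h arrays of the 2 lines, which by construction measures the difference between the lines summed over both times. The replicate block gave 3095 for the real groups, the batch term 3223 and replicates 2 and 3 only 7585. For the SND1 response beyond wt 1 of 100 gave as many (923, highest other 850), for the VND6 response minus the SND1 response 2 (117, highest other 328, which exchanged 0 h arrays of the lines), for the overlap of both lines, with the times regrouped, 1 (6691, highest other 24) and for the 9 list tests of responses 4 (5 calls, highest other 6), shares under 0.05 that again leave the pairs out of account. With the 0 h and 12 h arrays of each line and number kept together, the 10 regroupings of 2 lines are too few for such a share, and the highest other counts were 6 for the VND6 response beyond wt, 0 limma calls for the SND1 response beyond wt and 1 for their difference. With the times exchanged within these pairs, 1 of 32 regroupings, the real one, gave as large an overlap (highest other 24). That is a share under 0.05 only if replicates 2 and 3 are separate samples, since with these 2 moved together there are 8 regroupings, too few for such a share (highest other 24). Regrouping the times also breaks the changes that the lines share with wt cells. Such regroupings therefore cannot tell an overlap due to the factors from one due to estrogen and time. Of 100 regroupings of the 3 lines that keep the pairs, 7 gave as many list calls (highest other 5), so chance is not excluded for the lists.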

How the results depend on the processing

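Replicates 2 and 3 only, their average and the batch term were chosen after the data were seen. Quantile normalization, no filter, the stricter filter, no pseudocount, the larger pseudocount and no intensity trend each left all 8 counts within 1.5 times their value. Of 115 named values that passed, quantile normalization kept 110, no filter 107, no pseudocount 99, the larger pseudocount 115, no trend 114, the stricter filter 94 of the 98 it tested, only the arrays compared 84, the replicate block 113, replicates 2 and 3 only 113, the batch term 115, the average 47 and all single-array omissions together 83; 0 of the 115 changed sign in any of them. Of 102 named values that did not pass, 39 changed sign in some setting. Of the same 102, 15 passed under an alternative fixed beforehand and 32 passed with replicates 2 and 3 only. With 3 arrays per group and a pseudocount of 4.32, folds of dim probe sets are the least certain. Where no construction (fewer arrays, or other arrays estimating the spread) shows it, the cause was not tested.

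Fitting only the arrays compared gave 1049 calls for the VND6 response beyond wt, 45 for VND6 against wt at 0 h and 1 for SND1 against wt at 0 h. The replicate block gave 1658 for the SND1 response beyond wt and 583 for SND1 against wt at 0 h; for VND6 against wt at 0 h, where the numbers did not pair the arrays, it gave 1911, and the counts it gave for the remaining comparisons stayed within 1.5 times. The block ended 2 named calls, AT2G43870 and AT3G13820 in the difference of the responses, and changed no other named call and no list but auxin. Replicates 2 and 3 only gave 7585 for the VND6 response beyond wt, 5469 for the SND1 response beyond wt, 2586 for their difference, 7541 for VND6 and 4510 for SND1 against wt at 0 h. Averaging them, which leaves 2 values per group, gave 5238 for VND6 and 4955 for SND1 at 12 h against 0 h, 126 and 62 for the responses beyond wt, 12 for their difference, 0 for each line against wt at 0 h (limma, 1535 and 931 at an unadjusted p under 0.05), and overlaps of 2136 higher, 1844 lower and 399 lower without the probe sets called in wt. The batch term gave 1674 for the SND1 response beyond wt, 2262 for VND6 and 730 for SND1 against wt at 0 h.

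The 4 xylan tests were not run with the stricter filter, which left 3 of the 4 genes and so fewer than the minimum of 4. Where run, the 12 list tests kept their direction and their side of the threshold under the alternatives, apart from the values given here and the single-array omissions. For xylan, replicates 2 and 3 only gave an adjusted p = 0.0508 in the VND6 response beyond wt and 0.243 in the difference of the responses, and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, turned the direction in wt (adjusted p = 0.986). For auxin in the VND6 response beyond wt, the adjusted p was 0.0298 without a filter, 0.0328 with the stricter filter, 0.00408 with the replicate block, 0.0134 with replicates 2 and 3 only, and 0.0251 with the batch term; fry, a test of another hypothesis, gave 0.0483. In the SND1 response beyond wt it was 0.0297 without a filter, 0.0392 with only the arrays compared, 0.00408 with the block, 0.0134 with replicates 2 and 3 only and 0.0251 with the batch term. In the difference, the average turned the auxin direction (adjusted p = 0.996). Outside the single-array omissions, 22 of the 102 values that did not pass changed sign. Those among them printed in the report were GAMMA-VPE in the VND6 response beyond wt, which turned to 0.19 with replicates 2 and 3 only, and TIP41-LIKE in wt, which turned to 0.020 with the average.

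With 1 array left out, counts ranged from 7602 to 8484 in wt, 7285 to 8424 in VND6 and 6859 to 7212 in SND1 cells, 1099 to 3437 for the VND6 response beyond wt, 463 to 1041 for the SND1 response beyond wt, 66 to 194 for their difference, 540 to 2939 for VND6 and 102 to 846 for SND1 against wt at 0 h. The auxin adjusted p ranged from 0.0226 to 0.332 in the VND6 response, 0.0173 to 0.344 in the SND1 response and 0.164 to 0.982 in their difference. Of the values printed in the report that did not pass, those that changed sign were IRX10L in the VND6 response (-0.0848 to 0.467) and the SND1 response (-0.0912 to 0.409), PRX72 (-0.241 to 0.830) and ALPHA-VPE (-0.882 to 0.0661) in the SND1 response, GAMMA-VPE in the VND6 response (-0.384 to 0.224) and TIP41-LIKE in wt (-0.123 to 0.0621).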

Other observations

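Symbol families were tested after the data were seen, and none of their calls held with an estimated correlation (adjusted p = 0.513 or higher). Between 0 h and 12 h in wt cells, 7 of 8 tested ATG genes fell and 1 rose, over all genes and after quantile normalization alike, with a median log2 of -1.54 (camera adjusted p = 0.00108, and 0.513 with an estimated correlation). Most are ATG8 genes, whose proteins coat the autophagosome: ATG8H fell by 4.90, ATG8E by 4.80 and ATG8F by 3.48, while ATG8G rose by 0.68. In the VND6 and SND1 lines 7 of the 8 fell as well, with medians of -1.92 and -1.56. All 5 tested EXPA genes, expansins that loosen the wall, rose in wt cells with a median of 4.36, among them EXPA9 by 4.72 and EXPA8 by 4.36 (camera adjusted p = 0.0257, and adjusted p = 0.652 with an estimated correlation), and 3 of the 5 rose in each transformed line, under both scalings. EXPA20 rose by 2.14 in wt cells and had a smaller response in VND6 cells (-2.57, adjusted p = 0.00343) and in SND1 cells (-2.03, adjusted p = 0.0244). Of 6 NRPB genes, subunits of RNA polymerase II, 5 rose in wt cells under both scalings (median 2.04, camera adjusted p = 0.0452, and adjusted p = 0.652 with an estimated correlation).

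Of 5 TUB genes, beta-tubulins, 1, TUB6, rose more than in wt in VND6 cells (1.71, adjusted p = 0.000507) and in SND1 cells (1.37, adjusted p = 0.00498), and after quantile normalization 1 and 2 of the 5 did. The family stood higher than other genes in both (camera adjusted p = 0.0443 and 0.00539, and adjusted p = 0.652 in both with an estimated correlation), and in VND6 cells 4 of the 5 already stood higher than in wt at 0 h (median 1.16). No limma call against wt at 0 h held with replicates 2 and 3 averaged. Among 13 SCPL genes, serine carboxypeptidase-like proteins, 4 rose and 1 fell in the VND6 response beyond wt, and 3 rose in the SND1 response beyond wt (camera adjusted p = 0.0395 and 0.0443, and adjusted p = 0.652 in both with an estimated correlation). The 3 were SCPL48, scpl20 (5.54 in VND6 cells, 3.26 in SND1 cells) and scpl25 (1.91 and 2.88). The fourth in VND6 cells was scpl47 (2.31), and scpl26 was lower (-1.47), a call lost after quantile normalization. These genes were chosen after their values were seen, apart from SCPL48 and EXPA4.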
